A study of Mus musculus with 6 samples.

How the data were processed

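Total RNA of mouse jawbone periosteal cells was taken after 48 h of culture, per the labels' protocols, with a column kit, and sequenced on the DNBSEQ platform from circular single-stranded libraries. The reads were aligned with HISAT to GRCm38.p6, per the submitters' processing notes. The HISAT version, the counting tool, the annotation and any use of strand are not given in the sources used here. The authors deposited expected counts per gene, estimated read numbers that need not be whole, for each library. They also deposited FPKM values, which are normalised to gene length and library size, per the file headers. Between 28.9% and 30.6% of the count values in a library had decimals.

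Libraries were grouped by their titles into 3 spheroid and 3 monolayer libraries. The tables of both formats list the same 18002 genes, of which 17948 gene IDs matched RefSeq GRCm38.p6, the source of the coordinates given. Counts were rounded to whole numbers, after which the largest change of a library total was -0.000255%. Rows with low counts were removed with filterByExpr at a minimum count of 10, leaving 13708 genes. Genes were tested with edgeR 4.0.16 (R 4.3.3), using TMM factors between 0.985 and 1.02, robust quasi-likelihood fits and Benjamini-Hochberg adjustment over all tested genes, with a threshold of 0.05. Standard errors of log2 fold changes come from the test's F statistic. Where 1 group has few reads, such an SE is smaller than the counting error and understates the uncertainty. CPM values are counts scaled by TMM-adjusted library size, and means are given with the SD of 3 libraries.

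Replicate libraries were compared with each other before averaging. Over genes with at least 40 reads in a pair, the mean chi-square ratio of the pairs ranged from 1.90 to 2.91, above the value of 1 that counting noise gives, so no pair agreed within counting noise, as copies of 1 library would, and each library was counted once. Repeat preparations of 1 culture can also exceed that value, so the ratio does not show that the libraries came from separate cultures. A gene with 0 reads in a group was set against a floor of 3 reads over the group, which covers counting error only. The 95% interval for contractile genes against Myod1 is a bootstrap over 8 genes with 10000 resamples.

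The 37 gene lists, the tests of the 3 comparisons and the rule for named genes were fixed before the data were examined. The rule took 12 genes with the largest rise and 12 with the largest fall among those past the threshold, with no overlap between groups and at least 5 CPM in the higher group, leaving out clone-like and predicted gene names. It added, in each list, 2 members with the largest rise and 2 with the largest fall, and a fixed panel of genes of bone, actin, NF-kB and growth. Of the 37 lists, the 34 with at least 5 tested members were compared with all other genes by camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over lists. The result of 1 of these lists and those of some genes that the rule names are not reported here.

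The scripts were tested on simulated data with counts drawn from the means and spread of these libraries, in which 200 of 13585 tested genes were changed. The spheroid and monolayer test recovered 62% of genes changed 1.2-fold, 92% at 1.5-fold, 96% at 2-fold and 100% at 4-fold, and called 0.0747% of unchanged genes. The changed genes were drawn only from those above a minimum mean count, so recovery of low-count genes was not measured. A far smaller share of genes was changed in the simulation than was called in the data. The adjusted threshold depends on that share, so the 0.0747% does not carry over to the data.

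Alternatives were other scalings, other filters, DESeq2 1.42.0, limma-voom, limma on FPKM with pseudocounts of 1 and 0.1, a replicate block, stricter thresholds, an estimated correlation, fry and leaving out each library. A scaling by library size without the 10 most abundant genes and 7 further gene lists were added after seeing the data. The tests on cell-type shares, Myod1, Spp1 and mural cells were also chosen after the results were seen.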

Results

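RNA was profiled in primary mouse cells of the jawbone periosteum, the cell layer that covers bone and holds skeletal progenitors. The cells had been kept for 48 h either as spheroids, rounded aggregates formed by the cells themselves, or as a monolayer on a flat surface. Each culture format had 3 libraries, and total counts ranged from 21701010 to 21889071 per library over 18002 listed genes. The labels do not say whether the 3 libraries of a format came from separate cultures or animals. The p-values below therefore measure only the spread between these samples, which may be technical. That spread was small, with a median biological coefficient of variation of 3.09% per gene.

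The first comparison asked which genes differed between spheroids and monolayers. Spheroids held 26.5-fold more mRNA of Spp1, which encodes the bone matrix protein osteopontin, at 23090 ± 678 CPM against 870.1 ± 15.5 CPM in monolayers (SD, n = 3). They also held 279-fold more Saa3, an acute-phase protein gene, and 183-fold more Mmp3, a matrix-degrading protease gene. Acta2, the smooth muscle actin gene, was 16.9-fold lower in spheroids, at 269.7 ± 8.83 CPM against 4570 ± 46.6 CPM. In edgeR's quasi-likelihood test, 5082 of 13708 tested genes were higher and 5091 lower in spheroids at a Benjamini-Hochberg adjusted p below 0.05. Changes of at least 2-fold were found for 1746 genes that rose and 915 that fell. The groups did not overlap in CPM for 75.8% of tested genes, where chance gives 10%. On the log2(FPKM + 1) scale, which understates the change of low genes, limma gave 1408 genes with changes of at least 2-fold.

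Among genes with at least 5 CPM in the higher group, Saa3 (gene ID 20210, chromosome 7, 46711998 to 46719615, GRCm38.p6) had the largest rise, with a log2 fold change of 8.12 ± 0.09 (SE, adjusted p = 1.25e-35). Reads of Saa3 can be shared with the other serum amyloid A genes, so its level is uncertain. Ccl8, a chemokine gene, rose by 7.70 ± 0.17 on the log2 scale. Proteases followed, with Mmp3 at 7.51 ± 0.06, Mmp12 at 7.03 ± 0.13, Mmp9 at 6.99 ± 0.12 and Adamts15 at 6.71 ± 0.09. Sfrp4, a secreted Wnt antagonist, rose by 6.30 ± 0.06. Atp6v0d2, a proton pump subunit of osteoclasts, rose by 6.62 ± 0.17, Fbxo40, a muscle ubiquitin ligase subunit, by 6.53 ± 0.13, and Cck, which encodes cholecystokinin, by 6.23 ± 0.22. Several of these genes had few monolayer reads: Saa3 24, Mmp12 16, Atp6v0d2 12, Cck 8 and Ccl8 7. Their SEs therefore understate the uncertainty of the fold. The largest fall was in Megf6 (gene ID 230971, chromosome 4, 154170704 to 154275721), with a log2 fold change of -5.55 ± 0.07 (adjusted p = 4.09e-34). Cdh3, which encodes P-cadherin, and Cdsn, which encodes corneodesmosin, had log2 fold changes of -5.38 ± 0.15 and -5.03 ± 0.05. The citrate transporter gene Slc13a5 stood at -4.60 ± 0.14 and Nell2 at -3.95 ± 0.22. Contractile genes made up much of the rest, with Cnn1 at -4.13 ± 0.06, Actg2 at -4.09 ± 0.04, Lmod1 at -3.97 ± 0.07, Myl9 at -3.89 ± 0.04 and Tagln at -3.87 ± 0.04.

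**Figure D1:**
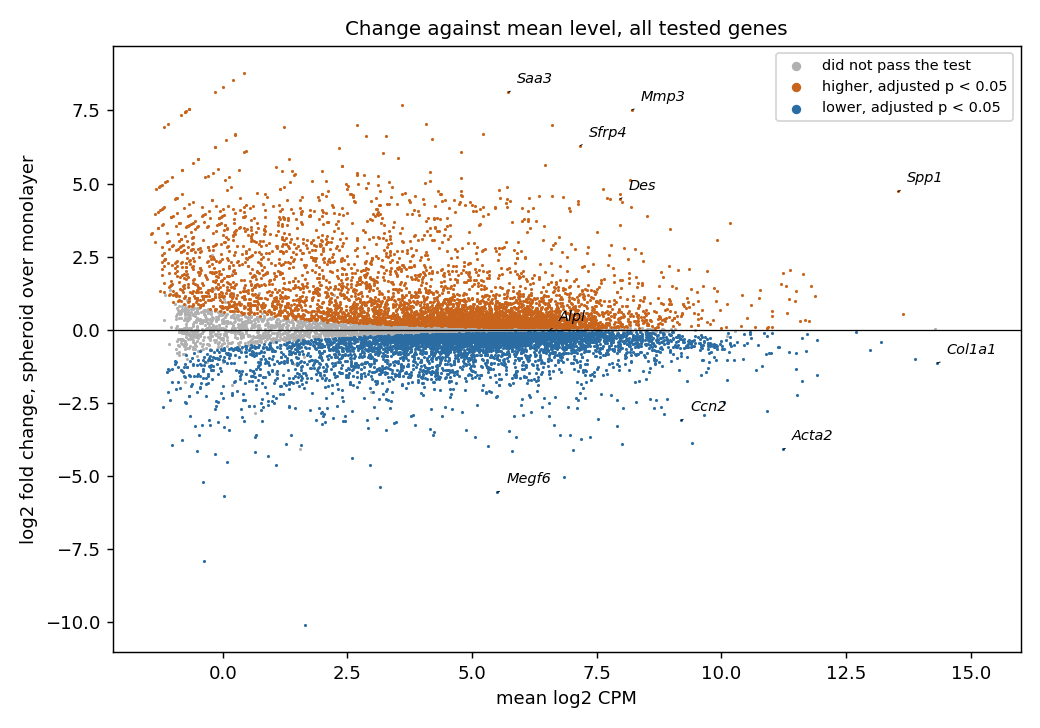
Each point is 1 of 13708 tested genes, with its mean log2 CPM over 6 libraries on the horizontal axis and its log2 fold change, spheroid over monolayer, on the vertical axis. Orange genes were higher and blue genes lower at an adjusted p below 0.05, and grey genes did not pass; Spp1 lies far right and high at 4.73, and Acta2 low at -4.08.

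The second comparison asked which gene groups moved together. It used 37 lists written before the data were examined, 34 of which had at least 5 tested members. Mineralisation genes, NF-kB targets, matrix proteases and markers of muscle, endothelium and osteoclasts were higher in spheroids. Actin and SRF/MRTF targets, YAP/TAZ targets, proliferation, cholesterol synthesis and integrated stress response genes were lower. With camera at a preset correlation of 0.01, 12 lists were called higher and 8 lower, and 11 of these 20 calls held with an estimated correlation. A list is said to be called where camera called it; fry, which asks whether a list moves one way without comparing it with other genes, called 30. Member counts adjusted over the list alone equalled those adjusted over all genes in every list except oxidative phosphorylation and leukocyte markers, where both are given.

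Of 22 tested genes of osteoblast matrix and mineralisation, 14 rose, 7 fell and 1 did not pass (camera adjusted p = 3.46e-06, and 0.0252 with an estimated correlation). Spp1 (gene ID 20750, chromosome 5, 104435111 to 104441053) had a log2 fold change of 4.73 ± 0.03 (adjusted p = 4.12e-41). Dmp1, a matrix protein gene of osteocytes, rose by 6.63 ± 0.19, from 0.139 ± 0.0467 CPM to 14.3 ± 0.640 CPM, and Ibsp, which encodes bone sialoprotein, by 1.43 ± 0.14. Dmp1 had only 9 reads in the 3 monolayers, so its SE understates the uncertainty. Bglap, which encodes osteocalcin, had 0 reads in the 3 monolayers and 120 in the 3 spheroids. It was at least 39.3-fold higher against a floor of 3 reads over the group, though reads can be shared with its near-identical copies. Alpl, the alkaline phosphatase gene, had 94.4 ± 2.86 CPM in monolayers and 94.6 ± 3.42 CPM in spheroids (log2 fold change 0.00 ± 0.04, adjusted p = 0.919). Collagen I mRNA was lower, with Col1a1 at -1.14 ± 0.03, and the osteomodulin gene Omd stood at -4.37 ± 0.16. Tnfrsf11b, which encodes the osteoclast inhibitor osteoprotegerin, had a log2 fold change of -3.59 ± 0.11. All 7 tested osteoclast markers rose in the same libraries.

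Among 14 osteogenic transcription factors 6 rose and 7 fell, and the list was not called (adjusted p = 0.843). Runx2, the master regulator of osteoblast fate, rose by 0.27 ± 0.04, and Sp7, which acts downstream of it, stood at -0.44 ± 0.05. Dlx3 rose by 2.34 ± 0.14 and Sox4 by 1.35 ± 0.03, while Atf4 stood at -0.86 ± 0.03. In this list the median was -0.12 and the mean 0.10. Periosteal and skeletal progenitor markers had 12 of 21 members higher and 6 lower (adjusted p = 1.33e-05). The adjusted p was 0.0963 with an estimated correlation. Cd200 rose by 4.43 ± 0.09 and Nes, the nestin gene, by 2.89 ± 0.07, against Ly6a at -1.15 ± 0.04 and Lepr at -0.70 ± 0.13. Markers of skeletal muscle and endothelium, whose cells can also express Nes, rose in the same libraries with medians of 4.08 and 2.65.

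Actin genes were lower in spheroids. Of 30 actin cytoskeleton and SRF/MRTF target genes 29 fell, with a median log2 fold change of -1.37 (camera adjusted p = 9.94e-59, and 0.0172 with an estimated correlation). Acta2 (gene ID 11475, chromosome 19, 34240336 to 34255585) stood at -4.08 ± 0.03 and Actb, the cytoplasmic beta-actin gene, at -1.24 ± 0.03. Reads can be shared among actin paralogs, so single actin values are uncertain. Tagln2 was the 1 member that rose, by 0.19 ± 0.03. The fall is stated for this list only. Immediate early genes, some of which SRF also drives, rose in 19 of 24 cases and fell in 4. Among them Fos rose by 3.73 ± 0.18 and Egr3 by 2.68 ± 0.06. That group was chosen after the results were seen, and its camera adjusted p was 0.0949 with an estimated correlation. YAP/TAZ targets had 16 of 22 members lower and 6 higher (adjusted p = 4.17e-06, and 0.0279 with an estimated correlation). Ccn2 and Ccn1, secreted matricellular proteins, stood at -3.09 ± 0.03 and -2.67 ± 0.04, while Ankrd1 rose by 2.26 ± 0.06 and Igfbp3 by 2.19 ± 0.04. Yap1 itself stood at -0.17 ± 0.03.

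Adhesion lists went both ways and were not called by camera. Integrins and focal adhesion genes had 8 of 27 higher and 14 lower (camera adjusted p = 0.117, fry adjusted p = 0.000347), with Itga7, a laminin receptor of muscle, at 3.00 ± 0.05 and Cav1, which encodes caveolin-1, at -2.46 ± 0.04. Cadherins and junction genes had 11 of 22 higher and 9 lower (camera adjusted p = 0.939, fry adjusted p = 0.0442), with Cdh15, the muscle cadherin, at 4.01 ± 0.12 and Cldn1 at -3.67 ± 0.29. Skeletal muscle markers rose in the same libraries. Mechanosensitive channels and sensors had 5 of 20 higher and 7 lower (adjusted p = 0.916), with Tead4 at 1.23 ± 0.10 and Kcnk2 at -1.06 ± 0.10. For junction genes the median was 0.06 and the mean -0.15, and for mechanosensors 0.02 and -0.02.

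NF-kB target genes were higher in spheroids, with 23 of 28 raised and 2 lowered (camera adjusted p = 2.03e-09, and 0.0239 with an estimated correlation). Their median log2 fold change was 1.10. Nfkbia, which encodes the inhibitor that NF-kB induces against itself, rose by 1.43 ± 0.05, from 20.9 ± 1.14 to 56.4 ± 1.47 CPM. Tnfaip3, another feedback inhibitor, rose by 1.28 ± 0.11, and Lcn2, the lipocalin-2 gene, by 6.07 ± 0.10. Csf1, a macrophage growth factor gene, stood at -1.03 ± 0.03 and Irf1 at -0.25 ± 0.06. Pathway components had 15 of 26 higher and 6 lower, and the list was not called (adjusted p = 0.216). Among them Rela rose by 0.20 ± 0.04, Nfkb1 by 0.31 ± 0.03, Tlr2 by 1.43 ± 0.07 and Tnfrsf1b by 1.31 ± 0.04, while Rel stood at -0.61 ± 0.10. Of the macrophage and leukocyte markers, whose cells also express such genes, 13 of 15 rose in the same libraries and 2 did not pass. The list had a median of 1.92, and its adjusted p was 0.07 with an estimated correlation.

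Matrix proteases and inhibitors had 18 of 24 members higher and 5 lower (camera adjusted p = 2.81e-15, and 0.0172 with an estimated correlation). Mmp3 (gene ID 17392, chromosome 9, 7445822 to 7455975) went from 3.20 ± 0.619 to 585 ± 7.74 CPM. The protease inhibitor gene Timp3 stood at -2.90 ± 0.03. Mmp9 also stands in the list of osteoclast markers, which rose in the same libraries with a median of 5.85, or 4.32 with Dcstamp at its bound. Of the macrophage and leukocyte markers 13 of 15 rose, with a list median of 1.92 and an adjusted p of 0.07 with an estimated correlation. Structural matrix genes had 17 of 30 lower and 11 higher (adjusted p = 3.58e-09), with Ogn at -3.72 ± 0.04, Col8a1 at -3.27 ± 0.04, Col5a3 at 2.05 ± 0.03 and Dcn, the decorin gene, at 1.39 ± 0.03. With an estimated correlation the adjusted p was 0.0609.

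All 30 proliferation genes fell, with a median of -1.39 (camera adjusted p = 2e-19, and 0.0366 with an estimated correlation). Mki67, the Ki-67 proliferation marker gene, went from 115 ± 0.352 to 54.3 ± 5.29 CPM, and the mitotic genes Tpx2 and Ccna2 stood at -1.71 ± 0.04 and -1.63 ± 0.04. Cholesterol biosynthesis genes fell in 24 of 25 cases, with a median of -1.49 (adjusted p = 1.85e-14, and 0.0172 with an estimated correlation). Of 20 integrated stress response genes 16 fell and 4 rose (adjusted p = 4.78e-11, and 0.0492 with an estimated correlation). Chac1 stood at -2.71 ± 0.07 and the amino acid transporter gene Slc7a3 at -2.49 ± 0.22, while Slc7a11, a cystine transporter gene, rose by 2.40 ± 0.05 and Atf3 by 2.31 ± 0.11.

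Other metabolic and stress lists were not called, though 2 of them were with no filter beyond 1 count in any library. Unfolded protein response genes had 15 of 19 lower and 3 higher (adjusted p = 0.0783, and 0.00257 with no filter), with Dnajb9 at 0.85 ± 0.04 and Herpud1 at -0.59 ± 0.03. Hypoxia and HIF targets had 13 of 26 higher and 10 lower (adjusted p = 0.122), with Angptl4 at 2.89 ± 0.04, Car9 at 2.45 ± 0.16, Vegfa at 1.28 ± 0.03 and Adm at -1.43 ± 0.07. Glycolysis genes had 6 of 17 higher and 8 lower (adjusted p = 0.916), with Eno2 at 1.40 ± 0.06 and Ldha, the lactate dehydrogenase A gene, at -0.54 ± 0.03. Oxidative phosphorylation genes had 1 of 30 higher and 11 lower, or 1 and 10 adjusted over the list alone (camera adjusted p = 0.399), with Uqcrq at -0.56 ± 0.04. Genes of p53 and apoptosis had 10 of 23 higher and 10 lower (adjusted p = 0.754), with Bcl2l11, a pro-apoptotic gene, at 1.65 ± 0.06 and Plk2 at -0.96 ± 0.04. The glycolysis median was -0.06 against a mean of 0.02, and the p53 median was -0.03 against a mean of 0.01. Interferon response genes had 10 of 17 lower and 0 higher (adjusted p = 0.092), with Ifi44 at -2.79 ± 0.71 and Isg15 at -2.60 ± 0.71. In edgeR's test both lost their calls with a replicate block (adjusted p = 0.0872 and 0.0907), at log2 fold changes of -2.74 and -2.54. Ifi44 also lost its call without monolayer replicate 2 or 3 or spheroid replicate 2 or 3 (0.056 to 0.0776), and Isg15 without any 1 library but monolayer replicate 1 (0.0647 to 0.0944). The interferon list was called without monolayer replicate 1, at an adjusted p of 0.00244, and with all 6 libraries and no filter, at 0.00418.

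Genes of neighbouring lineages moved in part. Chondrogenic genes had 6 of 12 lower and 2 higher (adjusted p = 0.00788), with Col2a1, the cartilage collagen gene, at -3.17 ± 0.15, Col11a1 at -3.04 ± 0.04, Sox9 at -0.36 ± 0.04 and Sox5 at 2.35 ± 0.14. The adjusted p was 0.19 with an estimated correlation and 0.11 with no filter. Adipogenic genes had 9 of 15 higher and 6 lower (adjusted p = 0.00126), and the adjusted p was 0.0608 with an estimated correlation and 0.0708 with no filter. Cd36, a fatty acid transporter gene, rose by 4.31 ± 0.12, and Plin1, a lipid droplet gene with 0 reads in monolayers and 49 in spheroids, was at least 16.05-fold higher. Muscle, endothelial and macrophage cells also express Cd36, and their marker lists had medians of 4.08, 2.65 and 1.92 in the same libraries. The last of these lists had an adjusted p of 0.07 with an estimated correlation. Pparg, the master regulator of fat cell fate, stood at -1.46 ± 0.08. Tendon and ligament genes had 4 of 9 higher and 4 lower (adjusted p = 0.917), with Egr1 at 2.34 ± 0.04 and Tnmd, the tenomodulin gene, at -3.02 ± 0.12. The tendon median was 0.03 and the mean -0.20. Wnt genes had 8 of 29 higher and 18 lower (adjusted p = 0.257), with Notum at 3.07 ± 0.11 and Dkk2 at -2.39 ± 0.10. BMP and TGF-beta genes had 8 of 27 higher and 16 lower (adjusted p = 0.299), with Tgfb1 at 2.77 ± 0.03 and Bmp4 at -2.68 ± 0.10. Angiogenic factors had 16 of 19 higher and 3 lower (adjusted p = 0.0252), with Flt1, a VEGF receptor gene, at 3.04 ± 0.09 and Vegfd at -2.26 ± 0.05. The adjusted p was 0.339 with an estimated correlation, and endothelial markers rose in the same libraries.

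Markers of most other cell types tested were higher in spheroids, while the few tested epithelial markers went both ways. The labels do not say whether both formats were started from the same mix of cells. All 11 tested skeletal muscle markers rose, with a median of 4.08 (camera adjusted p = 1.45e-41, and 0.0172 with an estimated correlation). Des, the desmin gene, went from 21.5 ± 0.290 to 477 ± 14.6 CPM, and Myh3, the embryonic myosin gene, rose by 4.47 ± 0.05. All 13 endothelial markers rose, with a median of 2.65 (adjusted p = 1.03e-13, and 0.0172 with an estimated correlation), among them Cldn5 at 4.83 ± 0.29 and Tie1 at 3.44 ± 0.09. Cldn5 had only 9 reads in monolayers, so its SE understates the uncertainty. All 7 tested osteoclast markers rose (adjusted p = 3.28e-11, and 0.0239 with an estimated correlation). Their median was 5.85, or 4.32 with Dcstamp at its bound. Dcstamp, a fusion gene of osteoclasts with 0 reads in monolayers and 61 in spheroids, was at least 19.98-fold higher. Schwann cell markers rose in 8 of 8 cases, with a median of 2.55 (adjusted p = 6.77e-06), and Erbb3 reached 3.24 ± 0.09. With an estimated correlation the adjusted p was 0.07. Macrophage and leukocyte markers had 13 of 15 higher, 14 adjusted over the list alone, and 0 lower (camera adjusted p = 0.00628). Cd68 stood at 3.16 ± 0.11 and Fcer1g at 2.79 ± 0.23, and the adjusted p was 0.07 with an estimated correlation. Mural cell markers, which cover the contractile cells around vessels, had 7 of 8 higher and 1 lower (adjusted p = 1.7e-06), with Kcnj8 at 3.68 ± 0.17 and Myh11 at -3.36 ± 0.12. With an estimated correlation the adjusted p was 0.0609. Des stands in both the mural and the muscle list, and without it 6 of 7 mural markers were higher, with a median of 1.06. The mural list leaves out contractile genes that fell, such as Acta2 at -4.08 ± 0.03 and Tagln at -3.87 ± 0.04. Of 4 tested epithelial markers Trp63 rose by 2.85 ± 0.24, Perp stood at -3.08 ± 0.18 and Krt19 at -2.47 ± 0.45. Red blood cell genes had 0 tested members and mitochondrially encoded genes were not analysed here.

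**Figure D2:**
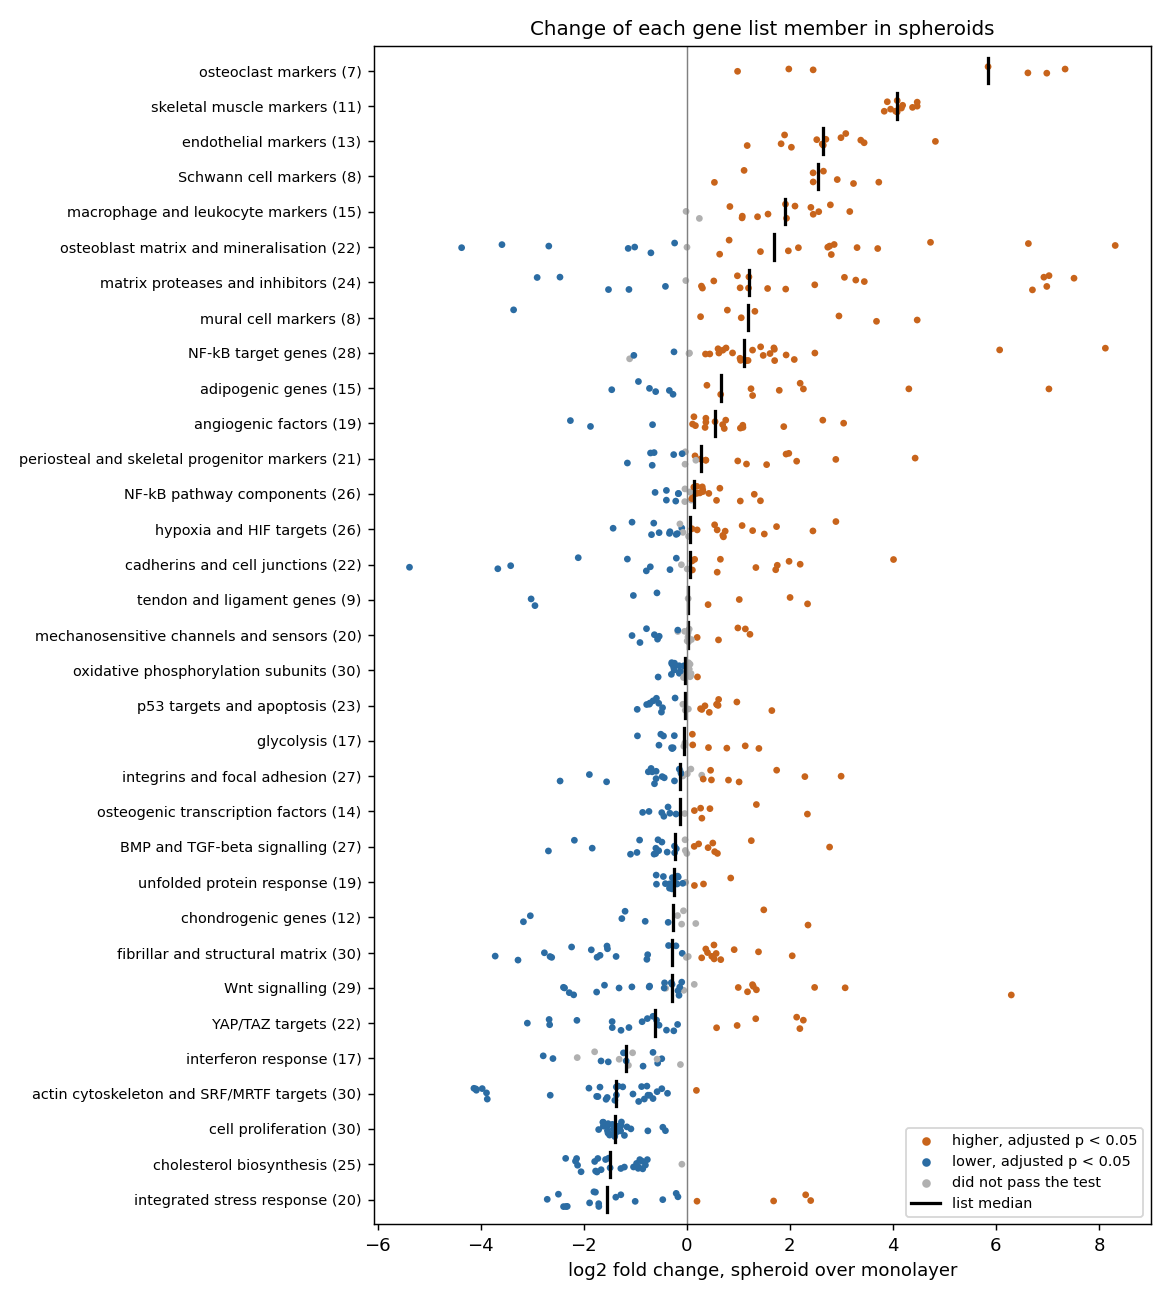
Log2 fold change, spheroid over monolayer, on the horizontal axis for each tested member of 33 lists, with the number tested in brackets and the list median as a black bar. Orange members were higher, blue lower and grey did not pass; the muscle median lies at 4.08 and the actin median at -1.37.

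**Figure D3:**
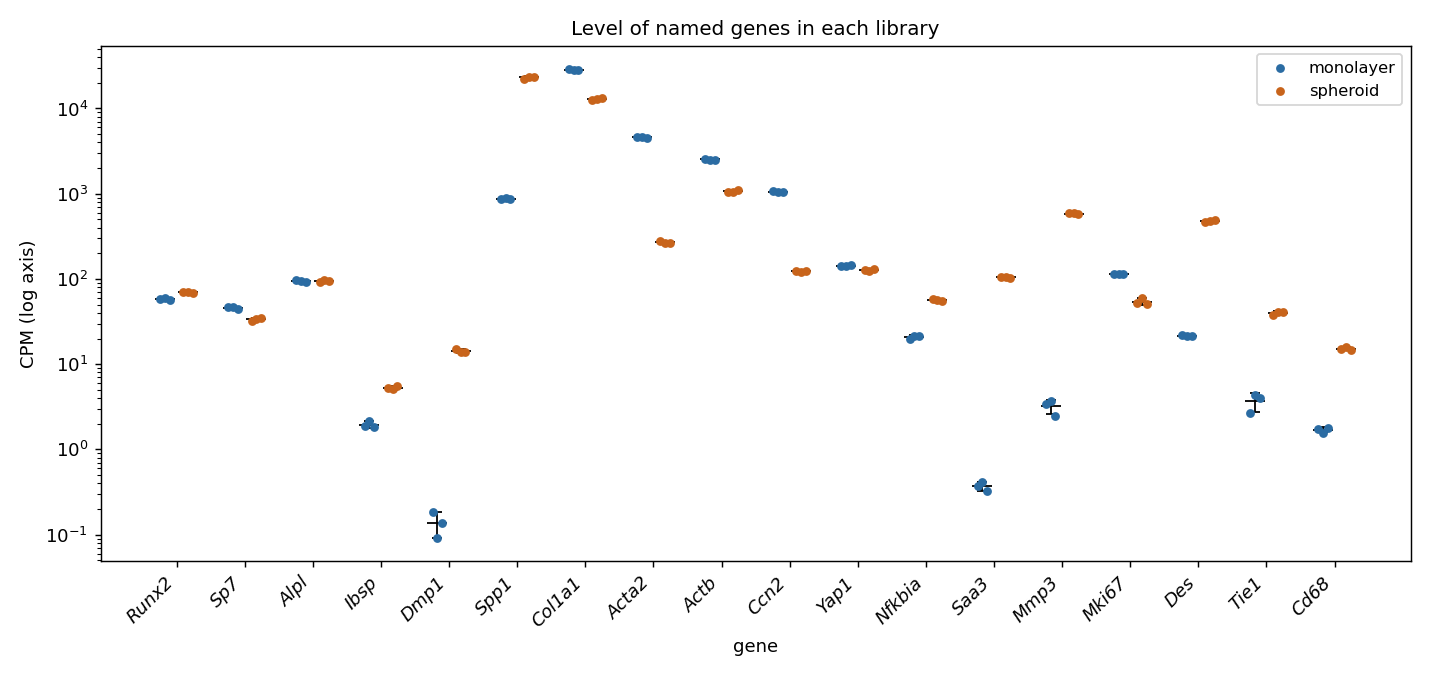
CPM on a log axis of 18 genes in each of 6 libraries, with points for libraries, short lines for group means and bars for 1 SD (n = 3). Spp1, Saa3, Mmp3 and Des sit higher in spheroids, Acta2, Ccn2 and Mki67 lower, and Alpl overlaps at 94.4 and 94.6 CPM.

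The third comparison asked how far the libraries of each format stood apart over all genes. The first principal component of log2 CPM separated spheroids from monolayers and held 92.5% of the variance, and the second held 2.33%. Pearson's r across genes was 0.994 to 0.995 between libraries of one format and 0.908 to 0.912 between formats. Genes are not independent replicates, and no test was made of these values. Col1a1 took the most counts in monolayers, at 2.80%, and Spp1 in spheroids, at 2.34%.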

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

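The scaling without the 10 most abundant genes was chosen after seeing the data, and all other alternatives before. The count of changed genes stayed between 8963 and 10712 under every alternative. Over the scalings the median log2 fold change of all genes ran from -0.02 to 0.03, and 48.4% to 53.5% of called genes were higher. The count of at least 2-fold changes stayed within 1.5 times of 2661 except with limma on log2(FPKM + 1), which gave 1408 genes, 945 higher and 463 lower, or 1406, 944 and 462 without a filter. The pseudocount shrinks changes of low genes by construction, and with 0.1 the count was 1936. Of the 20 called lists, 11 (6 higher, 5 lower) held with an estimated correlation, and fry, which asks whether a list moves one way without comparing it with other genes, called 30, of which 14 were lower. The share of the first component was 90.3% with a prior count of 0.5, 95.2% over the 500 most variable genes, 96.6% on log2(FPKM + 1), and 92.6% to 93.4% when 1 library was left out; the cause was not tested.

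Same-numbered libraries did not consistently deviate together, with correlations of -0.15, 0.24 and -0.12 for numbers 1 to 3, so the numbers were not taken to pair samples. Differently numbered libraries had correlations from -0.33 to 0.36, so a pairing in another order was not excluded. With a replicate block, 10238 genes changed, 2663 by at least 2-fold, and 20 lists were called.

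Of 148 named genes, 144 kept direction and call under every alternative that tested them. Alpl, never past the threshold, had a log2 fold change of -0.012 with upper-quartile factors, -0.0054 with no filter, and -0.022 to 0.030 with 1 library left out. Isg15 and Ifi44 lost their calls with the block, and Isg15 also without any library but monolayer replicate 1, Ifi44 without monolayer replicate 2 or 3 or spheroid replicate 2 or 3. Aldoc lost its call without monolayer replicate 3 or spheroid replicate 2. The interferon list, with an adjusted p of 0.092, was called without monolayer replicate 1 (0.00244), with no filter on low counts (0.00418) and by fry (0.0342), and lay between 0.0517 and 0.763 under its other alternatives. With no filter the unfolded protein response list was also called (0.00257), while the chondrogenic (0.11) and adipogenic (0.0708) lists lost their calls, and the number of called lists stayed at 20. The alternative for genes listed in 1 table was not run, since both tables list the same genes. Genes with few reads limit the folds of Bglap, Plin1 and Dcstamp to lower bounds.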

Other observations

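The gene groups in the next paragraph, and the tests on cell-type shares, Myod1, Spp1 and mural cells, were chosen after the results were seen. The camera p-values of these 7 gene groups were adjusted over the 7 alone. They describe the groups and give no independent support, since the groups were picked from the same results. The tests of other splits were written before. Those of scaling were written before their values were seen, for patterns taken from the results, and 1 of their 4 scalings, by library size without the 10 most abundant genes, was chosen after seeing the data.

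Lysosomal genes were higher in spheroids, with 41 of 45 raised and 4 lowered in edgeR's test and a median log2 fold change of 0.72 (camera adjusted p = 2.04e-15, and 0.00713 with an estimated correlation). Ctsb, the cathepsin B gene, rose by 1.95 ± 0.03 (SE) and Psap, the prosaposin gene, by 1.33 ± 0.03. Iron storage and NRF2 target genes rose in 15 of 16 cases (adjusted p = 1.11e-09, and 0.0431 with an estimated correlation), with Fth1, the ferritin heavy chain gene, at 1.52 ± 0.03 and the iron exporter gene Slc40a1 at 3.81 ± 0.08. Complement genes rose in 13 of 16 cases and fell in 2, led by C3 at 4.64 ± 0.04. The adjusted p for complement was 0.0556 with an estimated correlation. Macrophages and osteoclasts also express many lysosomal, iron and complement genes, and in the same libraries all 7 tested osteoclast markers rose, with a median of 5.85, or 4.32 with Dcstamp at its bound. Of the macrophage and leukocyte markers 13 of 15 rose and 2 did not pass, with a list median of 1.92 and an adjusted p of 0.07 with an estimated correlation. Immediate early genes rose in 19 of 24 cases and fell in 4, with Fos at 3.73 ± 0.18 and Egr3 at 2.68 ± 0.06, and the adjusted p was 0.0949 with an estimated correlation. Aminoacyl-tRNA synthetase genes fell in 19 of 20 cases, with Gars at -1.17 ± 0.03 (adjusted p = 4.89e-12, and 0.0295 with an estimated correlation). Ribosomal protein genes fell in 79 of 81 cases, with a median of -0.48, and the adjusted p was 0.182 with an estimated correlation. Sarcomere and muscle calcium handling genes rose in 33 of 34 cases, with a median of 4.28 and with Myh7 at 4.88 ± 0.07 (adjusted p = 8.53e-63, and 0.00713 with an estimated correlation).

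The marker lists of muscle, endothelial, Schwann and leukocyte cells were called higher in spheroids, the Schwann and leukocyte lists with an adjusted p of 0.07 each with an estimated correlation. The choice among these scalings is unlikely as the cause, since the lowest of the 4 list medians was 1.899 over the 4 other scalings. The scalings differed little, with a median log2 fold change of all genes from -0.02 to 0.03, so a larger scaling error was not examined. A lower share of the main cell type alone would raise all markers alike only if the main cells expressed none of them. The muscle median exceeded the leukocyte median by 2.168 (two-sided permutation p = 0.0081 over genes, which are not independent replicates). Expression of these markers in the main cells was not measured, so the difference cannot exclude a lower share of the main cell type. Maturation of a fixed number of Myod1-expressing cells, at constant Myod1 per cell, would leave Myod1 level and raise contractile genes well above it. Myod1 itself rose by 3.83 ± 0.09, which argues against this narrow case. The contractile median exceeded that of Myod1 by 0.251 (95% bootstrap interval 0.05 to 0.48 over genes, which are not independent). Maturation in which Myod1 also rises per cell cannot be told apart from a larger number of such cells by these values. A different mix of cells at the start, which the labels do not rule out, more surviving or retained cells of these types in spheroids, or induction of their genes by the culture format may each account for the pattern, and none of these was tested.

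Spp1 rose by 22220 CPM in spheroids. Leukocytes and osteoclasts as the source cannot be told apart from the periosteal cells themselves: their 22 tested markers together rose by 4.23% of that amount (4.11% to 4.42% over pairs of libraries), with Ctsk at 528 CPM, Mmp9 at 191 CPM and Lyz2 at 82.5 CPM. The ratio of Spp1 to these markers in such cells would have to be assumed, and Ctsk also stands in the list of periosteal markers. For this reason a first bound of 5%, under which such cells would have been set aside as the source, was given up after the value of 4.23% was seen. Induction of Spp1 by spheroid culture in periosteal cells may be part of the rise and stays open.

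The listed actin and SRF/MRTF targets were lower in spheroids, while immediate early genes outside that list, such as Fos and Egr3, rose. The highest list median over the 4 other scalings was -1.333, so the choice among these scalings is unlikely to be the whole cause. The scalings differed little, and a larger scaling error was not examined. Loss of mural cells cannot be told apart from a change within cells. Of the mural markers 7 of 8 rose (list median 1.19, SD over markers 2.43, camera adjusted p = 0.0609 with an estimated correlation). Without Des, which also stands in the muscle list, 6 of 7 rose, with a median of 1.06. The smooth muscle myosin gene Myh11, however, stood at -3.36. Contractile genes outside the mural list also fell, such as Acta2 at -4.08 and Tagln at -3.87, though such falls are the pattern in question. A first reading of the list median over 0 as evidence against a loss of mural cells was given up after its value was seen, because the markers went both ways. Loss of smooth muscle-like or other contractile cells, or lower actin-dependent transcription in rounded cells, may account for the pattern and stays open.

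The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 10173 genes, 2661 changed at least 2-fold, and 20 lists, and was the 1 split that reached each count. The highest of the other splits gave 0 genes, 0 and 15 lists. In edgeR these other splits had 18 to 41 genes with an unadjusted p under 0.05, and limma-voom called 0. Each of these other splits put both formats in each group, so the format difference counted as spread within groups. Few called genes follow from that by design, while part of the difference stayed between the groups. The other splits therefore give no measure of chance.

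The 17 tested interferon genes had a median log2 CPM of 3.22, 3.75 and 4.06 in monolayer replicates 1, 2 and 3, and of 2.83, 2.18 and 2.28 in spheroid replicates 1, 2 and 3.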
